A study of Mus musculus with 2 samples.

How the data were processed

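The series held 2 samples from primary gamma delta T cells of the thymus of C57BL/6 mice at postnatal day 0 to 3, 1 precipitated with a Notch1 antibody (clone D1E11) and 1 input without antibody. Per the labels' protocols, cells were fixed with 0.5% formaldehyde for 5 min, chromatin was prepared by sonication and enzymatic digestion, and libraries were amplified by 18 cycles of PCR. The submitters' processing notes name Bowtie 1.0.0, SAMtools 0.1.18 and genome build mm10, without their settings. The deposited peak list has no header and gives for each peak its position, a name that starts with MACS and a score. By the convention of early MACS versions such a score is a p-value on a negative log scale, but no header or label states that, so the deposited score was used only to describe, rank or filter peaks within the list. It is the authors' own value. A score of exactly 3100, shared by 38 peaks, can be a limit of the scoring and not a measured value, although 4 peaks lie above it. The version and settings of MACS, whether the input served as its control, how duplicate and multiply mapped reads were treated, and the read depth are not given in the sources used here. With 18 cycles of PCR and no molecular identifiers, stacks of duplicate reads and reads from repeated sequence can both raise a score, and neither can be measured from a peak list. The input library has no file of its own here and is not analysed, so no peak was set against background in the input. Samples were grouped by the antibody label, and with 1 Notch1 library no test between conditions was made.

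Peaks were set on the mm10 assembly (GRCm38) with the GENCODE release M21 annotation, and 0 peaks reached past the end of a chromosome. Intervals are reported from 1. A peak was called promoter if it overlapped by at least 1 bp the 1 kb on either side of any start site of a protein-coding gene, else exon, intron or intergenic, in that order. Random expectation came from 1000 placements of the same peaks on their own chromosome outside assembly gaps, with two-sided empirical p-values, and the repeat content used 100 of them. Peaks per chromosome were compared with 1000 draws by chromosome length without gaps, over 21 chromosomes. Shares carry Wilson 95% intervals, which cover counting error only.

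Motifs were scanned on both strands as presence or absence per peak. Up to 5 control regions per peak were drawn from the same chromosome, of the same width and promoter class and within 2 percentage points of GC content, outside peaks and gaps. Of the 5910 nuclear peaks, 10 had fewer than 5 controls, and 29507 controls were drawn. Drawing them from the same chromosome was stricter than the design fixed before the data were examined. Presence was compared by two-sided Fisher's exact tests, and promoter against distal peaks by the interaction term of a logistic model. The relation of the RBPJ core to score was tested by 100000 permutations of the mean score rank. A second set of 29432 controls was matched also on the share of soft-masked bases within 10 percentage points. Repetition was measured as the share of a peak's 32-base strings that occur more than once in the genome assembly.

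Gene lists (15 lists with 478 entries, 476 of them matched to a protein-coding gene) and 17 motifs were fixed before the data were examined, as were the tests and the rule for named genes. A gene counted as having a peak if one lay within 5 kb of any of its start sites, and each list was compared with all other protein-coding genes by a two-sided Fisher's exact test. Adjusted p-values are Benjamini-Hochberg values over the lists, motifs, classes or chromosomes tested together, with a threshold of 0.05. Genes are not replicates, and lists overlap. The lists covered Notch targets, the Notch pathway, the interleukin-17 and interferon-gamma programs, T cell receptor signalling, T lineage regulators, cytokine receptors with NF-kB, ribosomal proteins, replication, alpha beta thymocytes, B cells, myeloid cells, thymic stroma, liver and neurons. Named genes were all members of the Notch target, interleukin-17 and interferon-gamma lists with a peak, up to 12 each by score, up to 4 by score from every other list, 13 fixed genes whether or not they had a peak, and the 15 peaks of highest score with the nearest protein-coding start site. Some genes that this rule takes are not reported here. Exceptions are marked in the text as singled out after their values were seen.

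Alternatives changed 1 choice at a time, except that a window of the gene body was paired with random lists matched on gene length, nearest start sites came with a limit of 50 kb in place of 5 kb, and the subset of peaks with little repeat sequence combined a limit on soft-masked share with one on repeated strings. They covered the promoter window, the overlap that counts, the annotation, the threshold on score, flanks 3 kb away or shuffled sequence as controls, the central 200 bp, the list window, 10000 random lists matched on gene length or on promoter CpG ratio, and assignment to the nearest start site within 50 kb. Those on repeated 32-base strings, on matching by soft-masked share or number of start sites and on the windows with the most peaks were added after seeing the data. So was the subset with little repeat sequence. Leaving out peaks over 80% soft-masked was planned beforehand.

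The motif, promoter placement, chromosome, list and rank tests were checked on simulated data. The logistic interaction term and the placement test of repeat content were not. With regions that were not peaks standing in for the 5900 peaks that had 5 controls, 0 of 85 motif tests passed. Planting the RBPJ core in 5% of these regions gave an odds ratio of 1.25 (Fisher p = 1.36e-12). Of 500 random lists of 34 genes, 2.60% had a Fisher p under 0.05, against 93.0% of lists in which 30% of genes carried a peak on average and 52.8% where 20% did. Random placements called a promoter excess or deficit in 3.50% of 200 trials, and the permutation test of rank in 6.00% of 100. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.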

Results

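Binding of Notch1 to chromatin was profiled in gamma delta T cells, a lineage of T lymphocytes that carries a receptor made of a gamma and a delta chain. The cells were primary cells from the thymus of wild-type C57BL/6 mice at postnatal day 0 to 3. Chromatin immunoprecipitation with a rabbit monoclonal antibody against Notch1 was followed by sequencing (ChIP-seq), and 1 library was made with the antibody and 1 from input chromatin. Notch1 is a surface receptor whose intracellular domain, once released by cleavage, enters the nucleus and acts on DNA through its partner protein RBPJ. The stated purpose was to find the sites where the intracellular domain binds. The peak list of the Notch1 library held 5913 peaks on mouse build mm10, of which 5910 lay on nuclear chromosomes and 3 on the mitochondrial genome. With 1 Notch1 library there was no replicate, so every interval and p-value below describes the peaks, genes or regions of this library and not the spread between animals or preparations. The read depth is unknown from the files used, and the input library is not analysed here.

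The first question was whether genes known to answer to Notch signalling carried peaks. Of 32 genes on a list of known Notch targets, 6 had a peak within 5 kb of a transcription start site, namely Hes1, Il2ra, Gata3, Lef1, Relb and Runx1. That share of 18.8% compared with 8.81% of all 21938 protein-coding genes, of which 1933 had such a peak. The odds ratio against the remaining genes was 2.39 (95% interval 0.984 to 5.82), and the adjusted p was 0.108 by a two-sided Fisher's exact test over 15 lists, so the list did not pass the threshold. By the same exact test it passed with a window of 1 kb (odds ratio 4.26, adjusted p = 0.0160), with a window of 20 kb (2.80, adjusted p = 0.0175), and when each peak was given to its nearest start site up to 50 kb away, which changed the assignment and the distance together (4.12, adjusted p = 0.000608). At or above the median score 2 of the genes had a peak (1.25, Fisher adjusted p = 0.923), and in the upper quartile 1 did (1.201, adjusted p = 0.780). The list did not pass against random lists matched on promoter CpG ratio (1.964 times the matched mean, permutation adjusted p = 0.333), on number of start sites (2.03, adjusted p = 0.262) or, over gene bodies, on gene length (2.02, adjusted p = 0.0600). All 6 genes were also members of another list tested below.

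Hes1, a transcriptional repressor and a classical Notch target, carried the peak with the highest score of the 6. The peak spanned 520 bp on chromosome 16 from 30064211 to 30064730 and scored 1057. It covered the annotated start site of a processed Hes1 transcript at 30064384 and lay upstream of the protein-coding start site at 30065340. The peak itself held 0 copies of TGGGAA, the core sequence bound by RBPJ. The nearest core lay 68 bp upstream of it, at 30064138. A pair of cores in the Hes1 promoter, TGGGAAAGAAAGTTTGGGAA at 30065260 to 30065279, began 530 bp beyond the end of the peak.

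**Figure D1:**
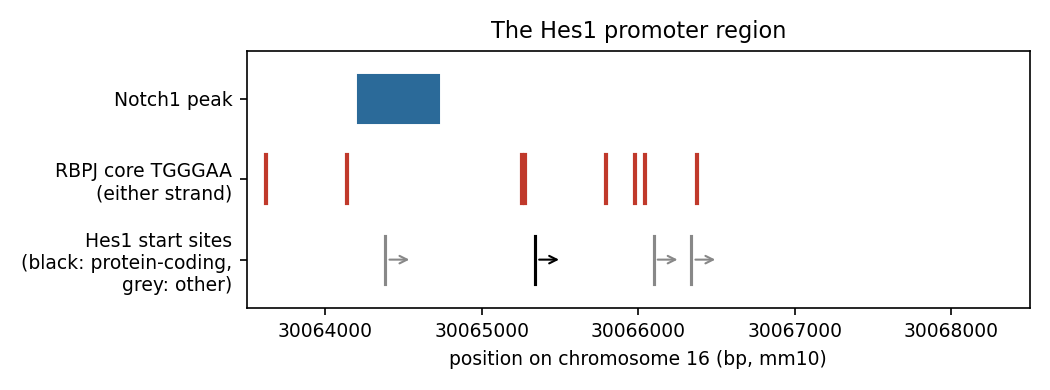
Map of the Hes1 promoter region, with position on chromosome 16 in bp (mm10) on the horizontal axis. The blue box is the Notch1 peak from 30064211 to 30064730, red ticks are RBPJ cores on either strand, and arrows are annotated start sites, black for the protein-coding one at 30065340. The paired cores at 30065260 to 30065279 lie between the peak and the protein-coding start site.

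Il2ra, which encodes the alpha chain of the interleukin-2 receptor, carried a peak on chromosome 2 from 11642967 to 11643415, 118 bp from a start site. That peak scored 766 and held 3 RBPJ cores. The Gata3 peak (chromosome 2, 9887398 to 9887748, score 704) lay 36 bp from a start site of this T cell transcription factor and held 1 core. The peaks at Lef1 (score 685), Relb (682) and Runx1 (649) lay at promoters and held 0 cores. Dtx1, Nrarp, Ptcra, Notch3, Notch1 and Myc, genes chosen beforehand, had no peak within 5 kb. The nearest peak lay 11.2 kb from a start site of Dtx1, inside Rasal1 and wholly in soft-masked repeat sequence. It lay 74.3 kb from Nrarp, 107 kb from Ptcra, 154 kb from Notch3, 155 kb from Notch1 and 238 kb from Myc. Of 41 genes on the Notch pathway list, 8 had a peak within 5 kb, among them the ligand genes Dll1 (score 1662) and Dll4 (834) and the co-regulator genes Ctbp1 (1109) and Kdm5a (847). The odds ratio of that list was 2.52 (1.16 to 5.45) and its adjusted p was 0.0530 by Fisher's exact test. It passed with a window of 20 kb (2.697, Fisher adjusted p = 0.00850), among peaks at or above the median score (3.22, adjusted p = 0.0494) and without peaks of repeated sequence (2.57, adjusted p = 0.0475). It did not pass with a window of 1 kb (1.99, Fisher adjusted p = 0.299), in the upper quartile of score (1.91, adjusted p = 0.624) or with nearest start sites up to 50 kb away (2.203, adjusted p = 0.0745). Nor did it pass against lists matched on promoter CpG ratio (1.65 times the matched mean, permutation adjusted p = 0.375), number of start sites (1.72, adjusted p = 0.268) or gene length (1.61, adjusted p = 0.133).

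Genes of both effector programs of gamma delta T cells carried peaks more often than other genes. Of 36 matched genes on the list for interleukin-17 producing gamma delta T cells, 11 (30.6%) had a peak within 5 kb, with an odds ratio of 4.57 (2.25 to 9.31) and an adjusted p of 0.000683. Blk, a Src-family kinase, carried the peak of highest score on this list, at chromosome 14 from 63377108 to 63377582 (score 1768, promoter). The scavenger receptor gene Cd163l1 followed, with an intergenic peak on chromosome 7 from 140215587 to 140216058 (score 1593). The others were Hes1, the interleukin-1 receptor gene Il1r1 (978), Il2ra, Gata3, Stat3 (703), Relb, Runx1, Ikzf2 (615) and the cytokine gene Il17f (532). Sox13, which encodes a transcription factor of this program, had no peak within 5 kb but an intronic peak 11.5 kb from a start site (chromosome 1, 133412477 to 133412871, score 828). The peak nearest to Il17a lay 9.50 kb away in intergenic sequence on chromosome 1 from 20740404 to 20740967 (score 1022). Among peaks at or above the median score, the list no longer passed (odds ratio 3.03, Fisher adjusted p = 0.0727).

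Of 34 genes on the list for interferon-gamma producing gamma delta T cells, 11 (32.4%) had a peak, with an odds ratio of 4.97 (2.42 to 10.2) and an adjusted p of 0.000512. Tnfrsf9, a costimulatory receptor gene, had the highest score, with a promoter peak on chromosome 4 from 150914884 to 150915090 (score 1232). Tbx21, which encodes the transcription factor T-bet, had a peak 794 bp from its start site on chromosome 11 from 97116125 to 97116400 (score 1215). Egr1 (945), Nfatc3 (852), the perforin gene Prf1 (805), Tnfrsf18 (764), the cytokine receptor genes Il12rb2 (746), Il2rb (742) and Il12rb1 (702), and the transcription factor genes Prdm1 (689) and Id2 (657) made up the rest. Ifng itself had its nearest peak 117 kb away. This list did not pass with a window of 1 kb (odds ratio 3.18, Fisher adjusted p = 0.0623), nor among peaks in the upper quartile of score (3.62, adjusted p = 0.147).

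Regulators of the T lineage, and receptors and signalling proteins of cytokines and NF-kB, held the highest shares of genes with a peak. Of 37 T lineage regulators 15 (40.5%) had one, with an odds ratio of 7.10 (3.68 to 13.7) and an adjusted p of 1.53e-06. The peaks of highest score were those of Zfp36l1 (3100) and Zfp36l2 (2213), which encode RNA-binding proteins, of the chromatin organizer gene Satb1 (1887) and of Tcf3 (1470), which encodes an E protein. Of 36 genes on the cytokine and NF-kB list 15 (41.7%) had a peak, with an odds ratio of 7.44 (3.83 to 14.5) and the same adjusted p. Stat5b (1622), Socs1 (1042), Ifngr1 (990) and Il1r1 (978) had the highest scores. Of 34 genes of T cell receptor and CD3 signalling 10 (29.4%) had a peak, with an odds ratio of 4.33 (2.07 to 9.07) and an adjusted p of 0.00125. They included the adaptor gene Lat (1464), the kinase gene Csk (1430) and the adaptor gene Pag1 (1401). This list did not pass among peaks at or above the median score (3.24, Fisher adjusted p = 0.0680).

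Cytosolic ribosomal protein genes, not specific to any cell type, also passed, with 13 of 51 (25.5%), an odds ratio of 3.56 (1.89 to 6.69) and an adjusted p of 0.00109. Rps14 (1761), Rpl24 (1610), Rpl4 (1474) and Rps19 (1458) had the highest scores. The Rpl24 peak lay 3571 bp from a start site of Rpl24 and overlapped Zbtb11, and the Rpl4 peak overlapped both Zwilch and Rpl4. That call ended against random lists matched on the CpG ratio of the promoter (adjusted p = 0.0520, a permutation of lists), with a window of 20 kb (Fisher, 0.0761) and with nearest start sites up to 50 kb away (0.469). The 6 lists that passed shared members, and of 66 different genes with a peak on them 9 were on at least 2. Il1r1, Il2ra, Stat3 and Relb were on the interleukin-17 list and the cytokine and NF-kB list. Gata3, Runx1 and Ikzf2 were on the interleukin-17 and T lineage lists, and Il2rb and Id2 were shared with the interferon-gamma list. Only Blk, Cd163l1, Hes1 and Il17f of the interleukin-17 genes with a peak were on no other list that passed. The interleukin-17 call is therefore not separate from those lists.

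Lists for other cells that a thymic preparation could hold did not pass. Of 24 alpha beta thymocyte genes 3 had a peak (Satb1 and Cd69 among them), with an odds ratio of 1.48 (0.441 to 4.96) and an adjusted p of 0.697. That list passed when each peak was given to its nearest start site up to 50 kb away (odds ratio 3.61, Fisher adjusted p = 0.00901). Of 20 B cell genes 1 had a peak (Bank1), as did 2 of 24 myeloid genes (Cebpe and Elane) and 2 of 23 thymic stroma genes (Dll4 and Col3a1). Among tissues not sampled, 1 of 23 liver genes (G6pc) and 0 of 24 neuron genes had a peak. Of 37 replication and cell cycle genes 4 had a peak, namely Mcm5, Ccnb1, Top2a and Pcna, with an adjusted p of 0.769. The Pcna peak lay 2388 bp from a start site of Pcna and overlapped Tmem230.

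**Figure D2:**
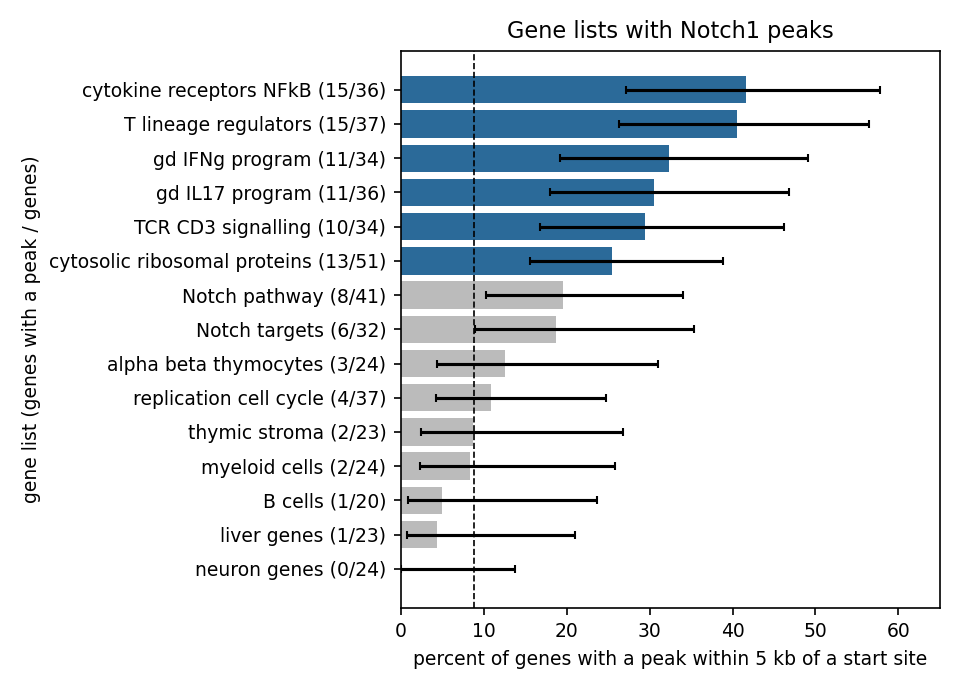
Percent of the genes of each list with a Notch1 peak within 5 kb of a start site, with Wilson 95% intervals. Blue bars passed an adjusted p of 0.05, grey bars did not, and the dashed line is the mean share of genes outside each list. T lineage regulators (40.5%) and cytokine and NF-kB genes (41.7%) stand highest, and 0 of 24 neuron genes had a peak.

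Antigen receptor loci were examined because T cells rearrange them. The Trg, Tra and Trd, and Trb loci together held 10 peaks, and the Igh, Igk and Igl loci held 3. Per Mb, this was 10.5 peaks in Trb, 5.72 in Trg (from 1 peak) and 1.11 in Tra and Trd, beside 2.23 over the nuclear genome, and 0.726 in Igh, 0.315 in Igk and 0 in Igl. These densities were not tested. Within Trb, 7 peaks lay between 41535337 and 41555039 on chromosome 6, over and beside the D, J and constant segments. The Trb peak of highest score (1620) spanned 41554008 to 41554577 between Trbc2 and Trbv31, the stretch known to hold the Trb enhancer, and held 2 RBPJ cores and 2 RUNX motifs. Trg held 1 peak, on chromosome 13 from 19182799 to 19183252 (score 844) between Tcrg-V7 and Tcrg-V4. Tra and Trd held 2 peaks, on chromosome 14 at 53878278 to 53878710 (score 1098) and at 54029095 to 54029445 (score 672). A further peak, singled out after its value was seen, lay 2904 bp beyond Trac toward Dad1, where the Tra enhancer is known to lie. It spanned 54227111 to 54227897, scored 3100 and held 2 RBPJ cores. The build carries these loci unrearranged, which the cells need not.

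Peaks lay at promoters more often than chance placement gives. Of the 5910 nuclear peaks 1173 (19.8%, Wilson 95% interval 18.9 to 20.9) overlapped the 1 kb on either side of a start site of a protein-coding gene. Placing the same peaks at random on their own chromosomes put 4.65% there on average, between 3.77 and 5.50% over 1000 placements. The observed share was 4.27 times the random mean, with an adjusted p of 0.00400 over 4 classes, from an unadjusted value of 0.002, the smallest that 1000 placements can give. Intergenic peaks were fewer than at random (42.8 against 57.5%, adjusted p = 0.00400, n = 5910 peaks). Exonic (5.08 against 4.77%, adjusted p = 0.282) and intronic peaks (32.3 against 33.1%, adjusted p = 0.237, n = 5910) did not pass. Exonic peaks passed as more frequent with a promoter window of 500 bp and by peak midpoint, and intronic peaks as less frequent with a window of 5 kb, with start sites of all genes and at or above the median and the upper quartile of score. From the lowest to the highest of 4 equal parts of the list by score, the promoter share was 16.4, 18.2, 21.3 and 23.5%.

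**Figure D3:**
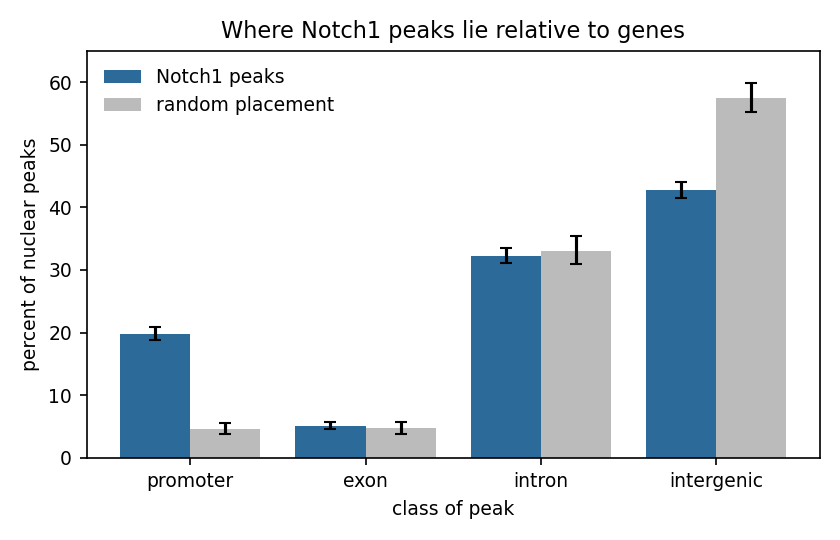
Percent of the 5910 nuclear peaks in each class (blue, Wilson 95% intervals) beside the same peaks placed at random on their own chromosomes (grey, mean of 1000 placements, bars from the lowest to the highest). Promoter peaks make up 19.8% against 4.65% at random.

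The sequence under the peaks was then compared with control regions of the same chromosome, width, promoter class and GC content. The RBPJ core TGGGAA was present in 29.5% of peaks and in 29.0% of controls, an odds ratio of 1.03 (0.964 to 1.09) with an adjusted p of 0.480 by Fisher's exact test over 17 motifs. The direction turned against flanking sequence (0.986), in peaks at or above the median score (0.972) and in the upper quartile (0.937), and none of these passed. Against the peaks' own sequence shuffled with dinucleotides kept, the core was more frequent (odds ratio 1.41, Fisher adjusted p = 1.51e-15), while a reversed core used as a control was less frequent (0.741, adjusted p = 1.85e-09). The core lay in 22.9% of shuffled sequences, less often than in the 29.0% of control regions, so that excess is not particular to peaks. The longer RBPJ consensus YGTGRGAA was found in 6.18% of peaks and 5.14% of controls (odds ratio 1.21, 1.08 to 1.37, Fisher adjusted p = 0.00419). It is not a mere extension of the core, since R stands for A or G and a site with A does not hold the core. The longer consensus also passed against flanks (1.18, Fisher adjusted p = 0.0339), against shuffled sequence (1.299, adjusted p = 0.00241) and in the 3241 peaks under 20% soft-masked with no repeated 32-base string (1.38, 1.19 to 1.61, adjusted p = 0.000249), whose controls were not limited in repeat content. That call ended with controls matched also on soft-masked repeat content (1.08, Fisher adjusted p = 0.278) in the central 200 bp (1.19, adjusted p = 0.0533), at or above the median score (1.205, adjusted p = 0.0782) and in the upper quartile (1.08, adjusted p = 0.554). Between promoter and distal peaks the odds ratio of the core did not detectably differ (ratio distal over promoter 0.922, 0.792 to 1.07, Wald p = 0.294, n = 5910 peaks). Peaks with the core ranked lower by score than peaks without it, by 2.37% of the list's length (permutation p = 0.00415), but were wider, with a median of 386 against 363 bp. Over the central 200 bp the difference was 0.295% (permutation p = 0.768).

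Motifs of other factor families were more frequent in peaks than in controls. Of 15 further strings, 1 of them a reversed RBPJ core used as a control, 10 passed with a higher frequency in peaks and 0 with a lower one. The ETS motif CCGGAAR was found in 5.18% of peaks and 3.30% of controls (odds ratio 1.6, 1.40 to 1.82, Fisher adjusted p = 2.01e-10). The RUNX motif was found in 17.6 against 14.2% (1.3, 1.2 to 1.40, with the same adjusted p). CACGYG, the E-box class of HES and MYC proteins, was found in 9.37 against 6.91% (1.39, 1.26 to 1.54, Fisher adjusted p = 8.08e-10). The NRF1 motif was found in 0.711 against 0.291% (2.45, 1.69 to 3.55, Fisher adjusted p = 2.49e-05). A lymphoid ETS motif (odds ratio 1.27) and the NF-kB motif (1.23) passed as well, and these 6 also passed against flanks, in the central 200 bp and with controls matched on repeat content. NF-kB did not pass against shuffled sequence (1.03, Fisher adjusted p = 0.890), at or above the median score (1.16, adjusted p = 0.245) or in the upper quartile (1.17, adjusted p = 0.389), nor did lymphoid ETS in the upper quartile (1.16, adjusted p = 0.341). CTCF (1.94), SP and KLF (1.28), ROR element (1.26) and AP-1 (1.2) motifs passed but lost the call in at least 1 of those settings. Against shuffled sequence the ROR element (0.885) and AP-1 (0.968) turned below 1, neither past the threshold. At or above the median score CTCF, SP and KLF and ROR element motifs did not pass, and in the upper quartile none of the 4 did. The HEB E-box (0.993), TCF and LEF (1.06), GATA (1.11) and YY1 (1.67) motifs did not pass, nor did the reversed core (1.01). YY1 passed against flanks (21.6, Fisher adjusted p = 0.000144), where 11 peaks and 1 flank held it, and against shuffled sequence (adjusted p = 0.00184). TCF and LEF (1.17, Fisher adjusted p = 0.000682) and GATA motifs (1.29, adjusted p = 0.000546) passed in the 3241 peaks with little repeat sequence.

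**Figure D4:**
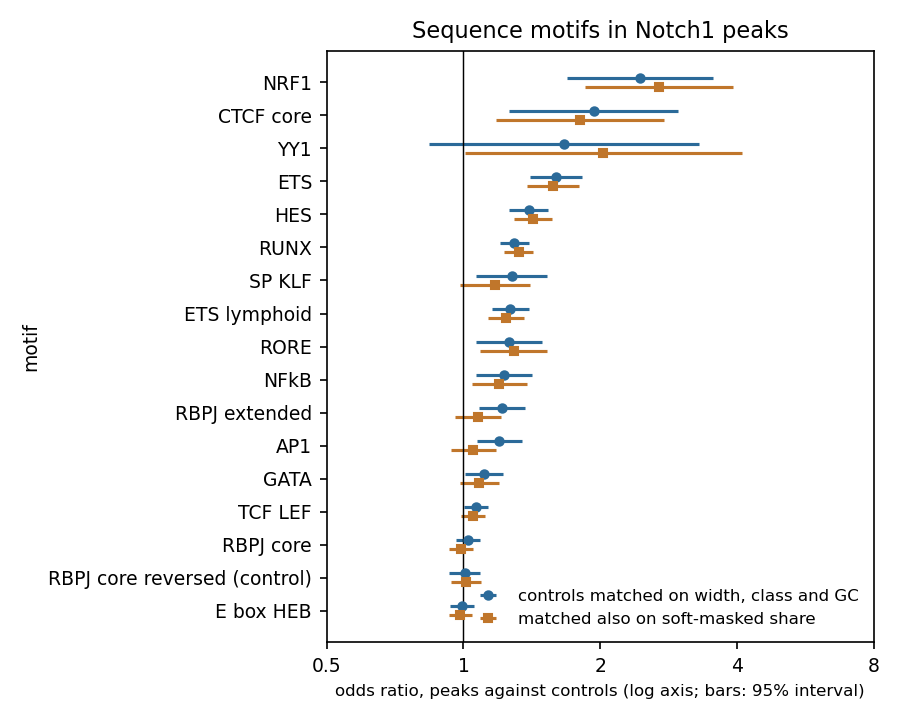
Odds ratio of each motif in peaks against control regions, on a log axis with 95% intervals. Blue points use controls matched on width, class and GC content, and orange squares use controls matched also on soft-masked share. ETS (1.6) and RUNX (1.3) have intervals above 1 with both controls, while the intervals of the RBPJ core (1.03) and the reversed core (1.01) include 1.

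Of the 15 peaks of highest score, 8 lay in sequence with little repetition. The Ccr9 peak, at chromosome 9 from 123756298 to 123757229 (score 3186), lay in an intron of this chemokine receptor gene. Peaks at a score of 3100 included one 21078 bp from a start site of Fasl, the Fas ligand gene, one at the promoter of Hivep2, one 45850 bp from Tnfaip3, a gene of an NF-kB inhibitor, and one 1314 bp from Zfp36l1. Others at that score lay 26017 bp from Dad1 (the peak beyond Trac), 12758 bp from the interferon-gamma receptor gene Ifngr2 and 67938 bp from Axin2. The remaining 7 had at least 20% of their 32-base strings repeated elsewhere in the genome. They were nearest to Gm10717 (a pair of peaks, the higher at 3221), Olfr1274-ps, Rab10, Gm21738, Ly6c2 and Filip1l. Because 38 peaks shared the score of exactly 3100, with 4 above it, 11 of the 15 were taken from a tie in file order. The score does not rank these peaks, and 3100 is not to be read as a measured signal.

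Peaks had a median width of 370 bp, from 148 to 5996 bp, and covered 2214550 bp. Scores ran from 55.4 to 3221 with a median of 718. Chromosomes 11 (472 peaks, 1.79 times the number its length gives), 17 (1.43 times) and 9 (1.29 times) held more peaks than placement by length, and chromosomes 14 (0.834), X (0.268) and Y (1 peak, 0.00509) held fewer, each with an adjusted p of 0.00699. The draws used length without gaps alone. Gene content, copy number and how well reads map to a chromosome were not allowed for. Chromosome 14 did not pass among peaks at or above the median score (0.855, adjusted p = 0.198, n = 2955 nuclear peaks). Mitochondrial peaks covered 66.8% of that genome, and 2 of the 3 scored 3100. Repeat sequence was less frequent in peaks than at random. Soft-masked bases made up 20.6% of the average nuclear peak and 33.5% of the same peaks placed at random (p = 0.0198, n = 5910, the smallest value 100 placements can give), and 96 peaks were over 80% masked against 802 at random.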

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

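The matching on soft-masked share and on number of start sites, the subset of peaks without repeats and the choice of the CA repeat came only after the data were seen, and the upper quartile of score and the longer consensus, settings chosen beforehand, were made tests of an explanation only after the result was seen. A difference between classes of peaks drew attention to the CA repeat ACACACAC, whose odds ratio against controls was 1.84 in distal and 1.28 in promoter peaks. The ratio of these odds ratios was 1.44 (1.14 to 1.81, adjusted p = 0.0156 over 8 motifs by the interaction term of a logistic model, n = 5910 peaks). For RUNX the ratio was 1.24, with an adjusted p of 0.0850.

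The RBPJ core was no more frequent in peaks than in matched regions. Dilution by peaks from repeated sequence is argued against by the 3241 peaks under 20% soft-masked with no repeated 32-base string, where the odds ratio was 1.06 (0.979 to 1.15), below the bound of 1.2 set for it. Dilution by peaks of low score is argued against by the upper quartile of score, with 0.937 (0.827 to 1.06). Duplicate reads and repeated sequence can also raise a score. That value therefore cannot decide on dilution by peaks without binding. A motif hidden at the centre is argued against by the central 200 bp, with 1.02 (0.947 to 1.10). Whether a core of 6 bases is too short to show binding stays open, since the longer consensus gave 1.08 (0.959 to 1.21) with controls matched on repeat content, an interval that reaches past the bound, and 1.38 (1.19 to 1.61) in those 3241 peaks, whose controls were not limited in repeat content. The longer consensus also matches sites without the core, so it does not vary length alone. No biological explanation was tested, and binding to chromatin through other proteins remains open. Access of any antibody to open chromatin remains open as well, since neither the input nor accessibility was analysed here.

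The highest scores lay in repeated sequence more often than the rest. Of 41 nuclear peaks with a score of at least 3000, 21 had 20% or more of their 32-base strings repeated, against 166 of 5869 others (odds ratio 36.1, 19.2 to 67.8, Fisher p = 1.61e-21), which is consistent with reads from many genomic copies piling up on one copy. Strings repeated in the assembly do not account for all of the highest peaks, since the share was 51.2% (36.5 to 65.7). Sequence that the cells hold in many copies but the assembly holds once was not counted. Pile-up therefore cannot be excluded for the other high peaks. Signal of the antibody and signal also present in the input cannot be told apart for these peaks, with 0 input files used. No biological explanation was tested.

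Gene lists of T cells, cytokine signalling and ribosomal proteins had peaks at more genes than other genes did. A preference for CpG-rich promoters whatever the gene does is argued against as the whole cause, since 5 of the 6 lists kept their call against random lists matched on promoter CpG ratio, the ribosomal list being the exception. Its odds ratio against all other genes was 3.56 (1.89 to 6.69). Against the matched lists its 13 genes were 2.004 times the mean of 6.49 genes of 51 (SD 2.38), a ratio of counts and not an odds ratio. That matched mean is a larger share than the 8.77% of the other genes. The adjusted p of the ribosomal list rose to 0.0520 by permutation of lists. A greater number of annotated start sites is argued against as the whole cause by all 6 lists keeping theirs against lists matched on it. It can still account for a part. The T cell receptor list was 2.41 times its matched mean (permutation adjusted p = 0.0306) and the ribosomal list 2.12 times (adjusted p = 0.0390), both weaker than against all other genes. Access of any antibody to open chromatin of expressed genes stays open, since neither expression nor accessibility was analysed here, and no biological explanation was tested.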

How the results depend on the processing

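The alternatives on repeated 32-base strings, on matching by soft-masked share or number of start sites, and on densest windows were chosen after seeing the data. So was the subset with little repeat sequence, while leaving out peaks over 80% soft-masked was planned. The promoter share stayed above its random mean and past the threshold under all 8 alternatives, from 15.3% with a window of 500 bp to 34.5% with 5 kb, whose random mean was 15.3%. Of the 5913 peaks, 2957 and 1480 remained at or above the median and the upper quartile of score, by construction, and 5680 after merging peaks within 500 bp. Chromosomes off the expected density numbered 6, and between 5 and 7 in the alternatives. T lineage regulators and the cytokine and NF-kB list passed under all 9 alternatives.

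The odds ratio of the RBPJ core turned below 1 against flanks (0.986), with controls matched on soft-masked share (0.988), at or above the median score (0.972) and in the upper quartile (0.937), none past the threshold. The longer consensus, which also matches sites without the core, passed over the main controls (1.21). The core passed against shuffled sequence (1.41), which held the core less often than control regions outside peaks did (22.9 against 29.0%). The ratio of distal over promoter odds ratios was 1.005 with a window of 5 kb. The score rank difference of peaks with the core was -0.295% of the list in the central 200 bp, no longer past the threshold. Peaks in the T cell receptor loci numbered 10, and 4 and 3 at or above the median and the upper quartile, since fewer peaks were used. Notch targets passed with windows of 1 kb (odds ratio 4.26) and 20 kb (2.80) and with nearest start sites (4.12), while their odds ratio fell to 1.25 at or above the median score and 1.201 in the upper quartile, where fewer peaks were used. The interleukin-17 list did not pass at or above the median score (3.03), nor the interferon-gamma list with 1 kb (3.18) or in the upper quartile (3.62).

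Directions of other motifs and of uncalled lists also turned, past the threshold for the CA repeat in peaks with little repeat sequence (0.467) and the reversed core against shuffled sequence (0.741). Against shuffled sequence the HEB E-box (1.06), GATA (0.996), ROR element (0.885) and AP-1 (0.968) turned too, as did the reversed core at or above the median score (0.993) and in the upper quartile (0.897), and TCF and LEF in the upper quartile (0.902). Against flanks these were the HEB E-box (1.06), TCF and LEF (0.996) and the reversed core (0.9996), and in the central 200 bp the HEB E-box (1.01). With a window of 1 kb it was the alpha beta list (0.799), and with 20 kb the myeloid (2.33) and stroma lists (1.296). In gene bodies the ratio to the mean of lists matched on gene length turned for the B cell (1.003) and myeloid lists (1.03). By odds ratio against all other genes, the B cell (1.01), neuron (1.14) and replication lists (0.891) turned there and the myeloid list (0.814) did not. At or above the median score the lists that turned were the alpha beta (0.814), myeloid (1.704), stroma (1.79) and replication lists (0.520), and in the upper quartile the B cell (1.961), liver (1.69) and replication lists (0.495). With nearest start sites these were the myeloid (1.58) and replication lists (0.727). As ratios to the mean of lists matched on CpG ratio, the myeloid (1.29), stroma (1.22) and replication lists (0.845) turned. With lists matched on start sites these ratios turned for the myeloid (1.27), stroma (1.17) and replication lists (0.995). Without repeated peaks the odds ratio of the stroma list turned (1.01). Where no construction is given, the cause was not tested. The unknown read depth limits how far a missing peak can be read as missing binding, and with 1 library no setting could test the spread between preparations. No pairing of samples was possible because each group had 1 sample. The motif tests pooled the controls and did not use the matching of each control to its peak.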

Other observations

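The items of this part were chosen after their values were seen, and no explanation was tested for them. Some windows of 100 kb were dense in peaks. Random spread of the peaks over the genome gave at most 5 peaks in such a window over 100 draws, and 20 windows held 6 or more. Those named here were picked by hand, and no group of genes was tested among them. Windows with 9 peaks lay at Nr4a1 on chromosome 15 (101240641 to 101275940), a gene induced by antigen receptor signals, and at Vps37b on chromosome 5 (124002158 to 124076673). Windows with 8 lay at Tnfaip3, at Selplg, which encodes a selectin ligand, and at Junb, which encodes an AP-1 subunit. The transcription factor gene Bach2 on chromosome 4 (32206351 to 32288458) had 6 peaks with a median score of 1374, and Smad3 on chromosome 9 (63714468 to 63758354) had 6 with a median of 617.

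Beyond the peaks named by rule, others at a score of 3100 with little repeated sequence lay at the promoters of Skil, Lmna and Junb, 2402 bp from Zfp36, which encodes an RNA-binding protein of activated T cells, and 328737 bp from Satb1 in intergenic sequence on chromosome 17 (52162027 to 52163324).

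Other dense windows had low scores or repeated sequence. Sfi1 and Drg1 on chromosome 11 held 43 peaks between 3100308 and 3198483, with a median score of 234 and a median of 12.6% repeated 32-base strings. A window at the start of chromosome 9 held 25 peaks with a median of 86.9% repeated strings. The Ugt1a cluster on chromosome 1 (88214659 to 88277610) held 9 peaks with a median score of 237 and a median of 0% repeated strings.

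All 32896 strings of 8 bases were ranked by their excess in peaks over the controls matched also on soft-masked share. The CA repeat ACACACAC came first. It was present in 14.7% of peaks and 9.06% of controls (odds ratio 1.74, 1.6 to 1.88), but among the 3241 peaks under 20% soft-masked with no repeated 32-base string it was less frequent than in their controls (0.467, 0.389 to 0.559), where leaving out soft-masked peaks by itself removes such repeats. The CRE, TGACGTCA, a binding site of CREB and ATF proteins, ranked at 6. It lay in 1.10% of peaks and 0.332% of the main controls (odds ratio 3.34, 2.44 to 4.57). Its odds ratio of 2.91 with controls matched on repeat content is the comparison that the ranking used, so it is no separate check. The intervals do not allow for the choice of these strings from the ranking.

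Narrow peaks carried high scores. The 79 peaks of 180 bp or less had a median score of 1721, and 6.33% of them lay at promoters (2.73 to 14) against 20% of wider peaks (Fisher p = 0.00150). A run of 6 CA units lay in the central 148 bp of 29.1% of them (20.3 to 39.9) and of 4.53% of wider peaks (Fisher p = 1.06e-12). Among the 126 wider peaks that scored at least the median of the narrow ones, the promoter share was 32.5% and the share with that run 4.76%.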
